A study of Homo sapiens with 9 samples.

How the data were processed

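RNA from tumours of MIA PaCa-2, a human pancreatic carcinoma cell line, was measured on 9 whole-transcriptome oligonucleotide arrays with human probes. The tumours grew in NMRI nude mice, which lack T cells. Mice received saline, an siRNA against GFP or an siLNA against GFP, with 3 arrays per group labelled as biological replicates. An siLNA is an siRNA in which some nucleotides are replaced by locked nucleic acid. Both RNAs were given by osmotic minipump at 0.25 mg/kg/day. The labels conflict on the length of treatment, giving 1 week in the sample protocols and 3 weeks in the series design.

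Per the labels' protocols, total RNA was extracted with Trizol, and biotinylated cRNA was prepared from 10 µg by the manufacturer's single-cycle procedure. The deposited table holds 1 linear intensity per probe set and array, for 54675 probe sets. The mean of these deposited intensities after leaving out the lowest and highest 2% was close to 100 on every array, so the values had been scaled to a common target. The software, background correction and summary method behind them are not given in the sources used here. No detection calls were used here.

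A gene name was taken only from the platform annotation supplied with the table. It gave a single gene symbol for 41097 probe sets and several for 1801, and it did not list 11777, which are unnamed here. The 62 control probe sets were left out of the tests and examined separately. No probe set is named for GFP in that annotation, so the target of both RNAs was not analysed here. The sequences of the siRNA and siLNA are not given in the sources used here, so seed matches were not tested.

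Intensities were converted to log2(signal + 16), which understates the change of dim probe sets, and every fold change here is on that scale. Array medians on it spanned 0.124, under the limit of 0.2 set for adding a normalization, so the deposited scaling was kept. Probe sets with a mean at or above the 40th percentile over all arrays were tested, which left 32768 and removed those under a signal of about 10.9. Group differences were estimated with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a single fit of all 9 arrays without a replicate block. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The fit compared siRNA with saline, siLNA with saline and siLNA with siRNA, and an F test asked for any difference among the 3 groups. With 3 arrays per group the median standard error of a log2 fold change was 0.204.

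Genes named in the text followed a rule set before the data were examined. It took the 12 largest rises and 12 largest falls per comparison among probe sets past the threshold that name a single gene and whose group values do not overlap, with 1 probe set per gene. Where fewer than 5 passed in a direction, the 5 smallest p-values were taken and are said not to have passed. Up to 4 members with the smallest p were named for each list called, and for the interferon, double-stranded RNA sensing, RNA interference and NF-kB lists. Members of other lists that passed are also given, and the text says that they lie outside the rule.

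A total of 21 gene lists was fixed at the same time. They covered interferon-stimulated genes, double-stranded RNA sensing, RNA interference machinery, NF-kB and inflammatory cytokines, hypoxia, cell cycle, p53 targets, the unfolded protein response, heat shock, immediate early genes, cholesterol biosynthesis, oxidative phosphorylation, ribosomal proteins, apoptosis regulators, TGF-beta response, epithelial and pancreatic tumour markers, and 5 lists of other cell types (fibroblast, endothelial, myeloid, erythroid, and muscle, fat and skin). Each was tested with limma's camera at a preset inter-gene correlation of 0.01 over 14033 genes, each represented by its probe set with the highest mean. The 4 tested members of the erythroid list were too few for the minimum of 5, and that list is only described. Signal on lists of stromal genes depends on how mouse RNA binds human probes and is not a share of cells.

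The pipeline was tested on simulated data built from the means and spreads of the 32768 probe sets, with 50 changes planted at each size. In the comparison of siRNA with saline it recovered 49 of 50 changes of log2 size 2, 19 of 50 of size 1 and 0 of 50 of size 0.5, with 3 false calls. For siLNA against saline it recovered 49, 22 and 2 of 50, with 12 false calls. For siLNA against siRNA it recovered 49, 25 and 0 of 50, with 6 false calls.

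To look for shifts shared by neighbouring genes, 14000 of the 14033 genes were placed in chromosome order by symbol with a RefSeq gene table of GRCh38.p14. The build of the array design is not named, so the table served for gene order only. Medians of log2 fold changes were taken over windows of 50 neighbouring genes in steps of 10 and compared with 1000 shuffles of the gene order. On 20 simulated gene orders the scan found a planted shift of 0.4 over 150 genes in 20 and gave 0 false detections. These orders were themselves random, like the shuffles they were compared with, so few false detections were to be had. The 0 therefore does not show how the scan behaves where neighbouring genes vary together. The turning point along each chromosome, set against 1000 shuffles of its genes, and the values per array on chromosome 9 were added after that scan had been seen.

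Alternatives set before the data were examined were quantile normalization, median centring, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, an intensity trend or robust fit in eBayes, array weights, a fit of only the groups compared, the replicate number as a block, and each array left out in turn. For the lists they were camera with an estimated correlation, limma's fry and another choice of probe set per gene. Leaving out siLNA replicates 1 and 2 together was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.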

Results

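The data describe 9 MIA PaCa-2 tumours grown in nude mice, 3 each from animals given saline, siRNA or siLNA directed against GFP, a jellyfish protein used as a reporter. The series design asks how each RNA altered tumour gene expression relative to saline. Both were infused at 0.25 mg/kg/day, for 1 week by the sample protocols or 3 weeks by the series design. Median signal per array lay between 17.5 and 20.4, and between 22.5% and 23.8% of all probe sets reached a signal of 100. The first principal component held 23.7% of the variance and placed the siRNA arrays between 31.7 and 36.6, the saline arrays between -13.2 and 1.63 and the siLNA arrays between -45.1 and -9.48.

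Tumours of siRNA-treated mice differed from saline tumours past the threshold in a limited set of genes, several of them by more than 10-fold. That set does not bound the extent of the difference, because the simulation recovered 19 of 50 changes of log2 size 1 and 0 of 50 of size 0.5. The tight junction gene CLDN11 rose from a signal of 39.4 ± 1.33 to 1581 ± 269 (SD, n = 3), a log2 fold change of 4.84 ± 0.17 (SE, limma adjusted p = 3.14e-06). RTN1, which encodes a reticulon of the endoplasmic reticulum, rose by 4.75 ± 0.26 on the log2 scale, and GAS1, a growth-arrest gene encoding a hedgehog co-receptor, by 4.41 ± 0.22. SELENOP, encoding a secreted selenium carrier, rose by 3.65 ± 0.21. On the log2(signal + 16) scale the largest fall was that of the gap junction gene GJB2, from 244.2 ± 47.6 to 17.97 ± 1.99 (SD, n = 3), with a log2 fold change of -2.92 ± 0.24 (SE, limma adjusted p = 0.000811). The order of the falls depends on the pseudocount, because signals in siRNA of 4.1 for AMOTL1, 2.17 for CDH18 and 4.63 for DSC1 lie under the filter level of 10.9, so their falls are bounds.

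Of 32768 probe sets, 169 passed the threshold in siRNA against saline, 84 higher and 85 lower, naming 62 and 68 genes. All 169 separated the groups without overlap, as did 20% of all tested probe sets, against 10% from chance with 3 arrays against 3. At an unadjusted p of 0.05, 4214 probe sets passed, where 1638.4 would pass by chance. Changes of at least 4-fold were found in 13 higher and 9 lower probe sets. The other named rises were ZNF488 (log2 fold change 3.41), C6orf15 (2.62), the cytoskeletal adducin ADD3 (2.16), TSPAN18 (2.12), the G protein subunit GNAL (2.03), TANC1 (1.98), the corepressor TLE2 (1.95) and the TGF-beta receptor TGFBR2 (1.85), with adjusted p between 0.000518 and 0.0428. Named falls after GJB2 were the angiomotin family gene AMOTL1 (-2.58), LOC646736 (-2.42), the cadherin CDH18 (-2.17), NAV3 (-2.13), MDFIC (-2.13), the desmosomal cadherin DSC1 (-2.04), FRMD4B (-1.995), the antiviral deaminase APOBEC3G (-1.84), PKD1L1-AS1 (-1.83), the guidance receptor ROBO1 (-1.77) and the sodium channel subunit SCNN1A (-1.75). A second probe set was tested for GAS1 and did not share its rise (log2 fold change -0.20, adjusted p = 0.843), while all 3 further probe sets of ADD3 and the further ones of RTN1 and TLE2 rose past the threshold. Further probe sets of TSPAN18, GNAL, TANC1, AMOTL1, NAV3, MDFIC and SCNN1A shared the sign of the named ones and did not pass.

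The count fell when any siRNA or saline array was left out, to between 34 (without siRNA replicate 1) and 104 (without saline replicate 3). Calls for TSPAN18, GNAL, TLE2, TGFBR2, DSC1, PKD1L1-AS1 and SCNN1A were then lost for at least 2 choices of the array left out, at adjusted p between 0.0509 and 0.165. With a pseudocount of 1 the calls for ZNF488 (adjusted p = 0.0735, from a saline signal of 6.97 ± 8.78, SD, n = 3), TSPAN18 (0.196), GNAL (0.157), TLE2 (0.122), TGFBR2 (0.0913) and DSC1 (0.0569) were lost, and that for TLE2 also under quantile normalization (0.0504).

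**Figure D1:**
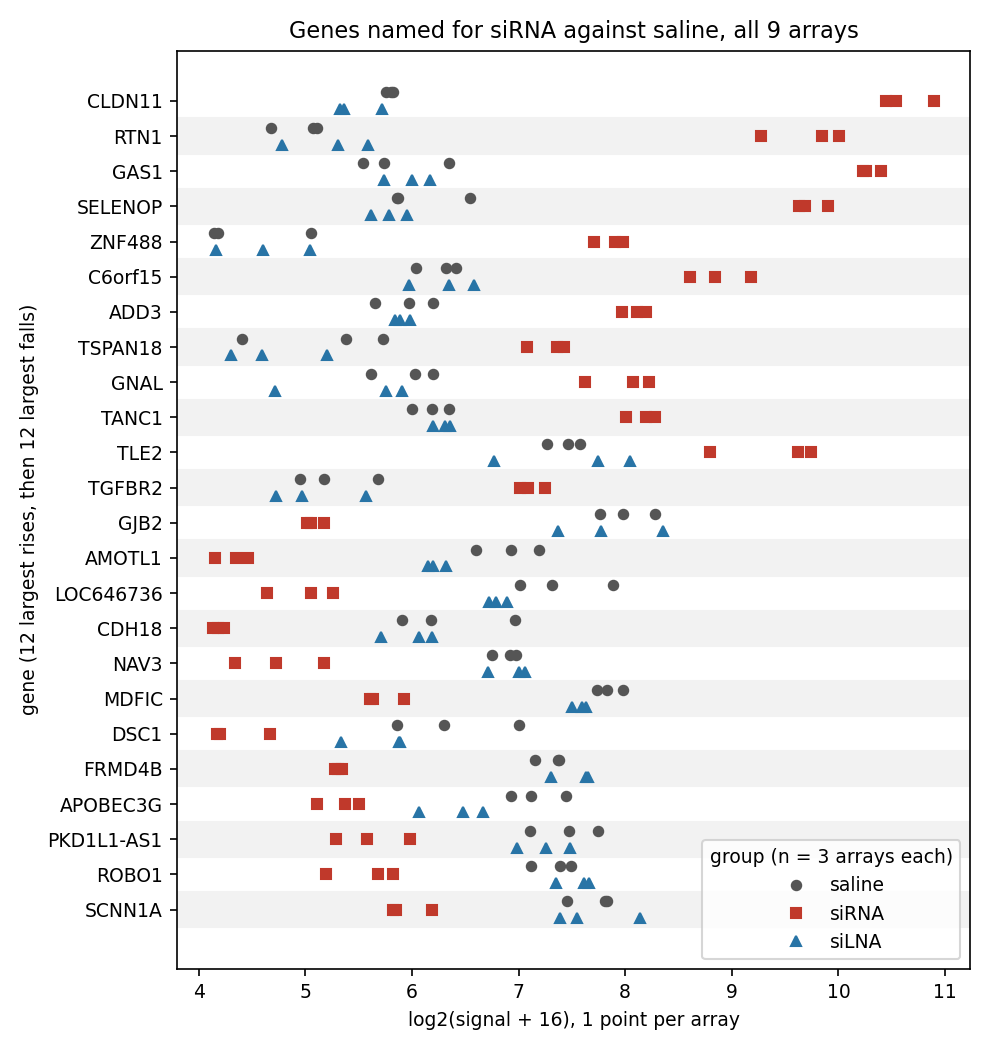
Signal of the 24 genes named for siRNA against saline, as log2(signal + 16) on the horizontal axis, with 1 point per array and 3 arrays per group (circles saline, squares siRNA, triangles siLNA). In each gene the siRNA arrays stand apart from the saline arrays, as the naming rule required, and from the siLNA arrays too.

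Genes of chromosome 9 shifted together in the siRNA tumours. The window of 50 neighbouring genes from MRPL50 to WHRN had a median log2 fold change of 0.52 against saline, where the largest of 1000 shuffles of gene order reached 0.24. Along that chromosome the change turned between FRG1JP and ZNF658, next to the centromere. Of the 144 genes before the turn, on the short arm, 120 were lower (median -0.34), and of the 418 after it 350 were higher (median 0.39). The median after minus the median before was 0.745 ± 0.036 in siRNA, -0.004 ± 0.029 in saline and 0.047 ± 0.044 in siLNA (SD, n = 3 arrays each). The 3 siRNA arrays lay between 0.713 and 0.783 and the 6 others between -0.026 and 0.076. The chromosome and the turn were chosen from these same arrays, so no p-value is given for them. Of 109 called genes with a place in the gene order, 13 lay on chromosome 9, or 11.9% against 4.01% of those tested. All 3 called genes before the turn fell and all 10 after it, GAS1 among them, rose. Over all chromosomes, 25 of the 109 had another called gene within 10 places, where shuffled calls gave a median of 15 and 34 of 1000 shuffles gave as many. Smaller steps were found on chromosome 5, with medians of -0.15 over the 72 genes up to TARS1 and -0.04 over the 557 after it (0 of 1000 shuffles as large), and on chromosome 6, with 0.07 over the 92 genes up to CARMIL1 and -0.13 over the 653 after it (1 of 1000 as large). In siLNA against saline chromosome 8 stepped to 0.17 over the 68 genes from JRK on. Chromosome 20 stepped to 0.27 over the 59 from PPP1R3D on and chromosome 9 to 0.11 over the 178 from LRSAM1 on. In each, 0 of 1000 shuffles gave a step as large, and on chromosomes 4, 5, 11, 16, 17 and 19 from 1 to 7 did. For siLNA against siRNA, 0 of 1000 did on chromosomes 6, 8, 9 and 11. Steps near or beyond the shuffles were thus spread over several chromosomes, and shuffled gene order does not allow for neighbouring genes that vary together. The largest chromosome 20 window lay at 0.37 and 0.41 on siLNA replicates 1 and 2 but at 0.08 on replicate 3. The late part of chromosome 9 was likewise raised mainly on replicates 1 and 2.

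**Figure D2:**
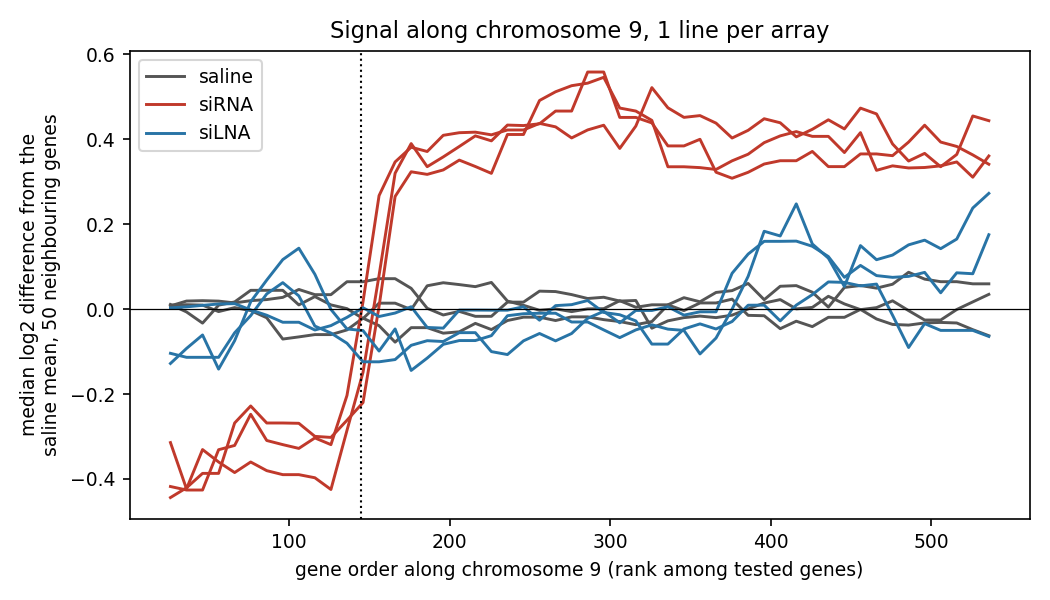
Median log2 difference from the saline mean over windows of 50 neighbouring genes (vertical axis) along the order of the 562 tested genes of chromosome 9 (horizontal axis), with 1 line per array coloured by group. The dotted line marks the turn after 144 genes, where the 3 siRNA lines cross from below to above 0; the saline lines stay near 0, and 2 siLNA lines lie above it in the last part.

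Among the lists, the hypoxia response was lower in siRNA tumours, with a median log2 fold change of -0.52 and 28 of 31 tested members below 0. Only the glucose transporter SLC2A3 fell past the threshold (-1.38 ± 0.21 SE, adjusted p = 0.0249), none rose and 30 did not pass, and 11 fell when adjusted over the list alone. Collagen prolyl hydroxylases P4HA2 and P4HA1 had values of -1.23 (adjusted p = 0.051) and -0.88 (0.106), and the mitophagy receptor BNIP3L of -0.65 (0.139). Camera gave the hypoxia list an adjusted p of 1.13e-08, and adjusted p = 0.72 with an estimated correlation. The heat shock list had a median of -0.13 over 18 members (adjusted p = 0.0183, and adjusted p = 0.72 with an estimated correlation). None of its members passed and 1 fell when adjusted over the list alone, with HSPB1 at -0.66 and HSPA4L at -0.63. The unfolded protein response and amino acid stress list had a median of -0.14 over 32 members (adjusted p = 0.0352, and adjusted p = 0.477 with an estimated correlation). None of them passed by either adjustment, with VLDLR at -0.71, ASNS at -0.66 and PSAT1 at 0.68. The cell cycle list had a median of 0.14 over 48 members (adjusted p = 0.0198, and adjusted p = 0.886 with an estimated correlation), with BUB1B at 0.54 and CCNE2 at 0.52 but MELK at -0.43, and none passed by either adjustment.

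The lists tied to double-stranded RNA were not called for siRNA. They were read on human probes, so a response in cells of the mouse host was not measured as such. None of the 38 interferon-stimulated genes passed (list median -0.08, camera adjusted p = 0.551), with IRF7 at -0.94 (adjusted p = 0.0754), OAS3 at 0.61 (0.162), BST2 at -0.80 (0.232) and PARP9 at 0.47 (0.276), and 1 fell when adjusted over the list alone. None of the 20 genes of double-stranded RNA sensing passed (median -0.06, adjusted p = 0.715), with EIF2S1 at -0.28, EIF2AK2 at 0.27, RIGI at -0.28 and ZC3HAV1 at -0.24. None of the 26 RNA interference genes passed (median 0.06, adjusted p = 0.659), with AGO2 at -0.54 (adjusted p = 0.193), TNRC6A at 0.42, GEMIN4 at 0.28 and DCP2 at 0.32. None of the 26 NF-kB and inflammatory cytokine genes passed (median -0.06, adjusted p = 0.663), with CXCL8 at -1.16 (adjusted p = 0.154), PLAU at -0.82, IER3 at 0.65 and CCL5 at 0.42. Adjusted over the list alone, 1 of the NF-kB genes rose and 2 fell.

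Members of other lists that passed, SKIL, FAS and VCAN, lie outside the naming rule. In the TGF-beta list, TGFBR2 and the SMAD corepressor gene SKIL (1.54 ± 0.20 SE, adjusted p = 0.0158) rose past the threshold and 17 of 19 did not pass. Adjusted over the list alone, 6 rose and 2 fell, and the list as a whole was not called (median -0.02, mean 0.25, adjusted p = 0.373). The death receptor gene FAS, on the p53 list, fell by 1.29 (adjusted p = 0.0464) in a list not called (median -0.05, adjusted p = 0.449). VCAN, which encodes the matrix proteoglycan versican and is on the fibroblast list, rose by 1.46 (adjusted p = 0.0201), while 22 of the 23 genes tested on that list did not pass (median -0.08, adjusted p = 0.659). Medians of the other lists were -0.09 for immediate early genes, -0.09 for cholesterol biosynthesis, 0.05 for oxidative phosphorylation, 0.01 for ribosomal proteins, 0.01 for apoptosis regulators and -0.14 for epithelial and pancreatic tumour markers, with adjusted p between 0.373 and 0.747. Among other cell types the medians were 0.16 for endothelial genes, 0.03 for myeloid genes and -0.01 for muscle, fat and skin genes (adjusted p between 0.659 and 0.953). The 4 erythroid genes had a median of -0.27. None of the lists kept its call with an estimated correlation or under fry, and the call for the unfolded protein response was lost without any 1 of 6 arrays (adjusted p up to 0.289), that for heat shock without saline replicates 1 or 2 or siRNA replicate 1 (up to 0.222), and that for the cell cycle without saline replicate 2 or siRNA replicate 3 (up to 0.252).

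Tumours of siLNA-treated mice showed no probe set past the threshold against saline. The lowest adjusted p was 0.251 (limma), and 3429 probe sets passed at an unadjusted p of 0.05, 2330 higher and 1099 lower, where 1638.4 would pass by chance. Other splits of the same 6 arrays, which mix the groups, gave up to 3082. Groups did not overlap in 16% of probe sets, against 10% from chance. The genes with the smallest p, none of which passed, were MIER2 (log2 fold change 1.19 ± 0.16 SE), the DNA damage histone gene H2AX (1.08 ± 0.16), the calcium channel gene CACNA1C (0.93 ± 0.15), ANKRD36B (0.99 ± 0.16) and ARHGAP25 (0.87 ± 0.14) among those higher. Among those lower they were ACKR5 (-0.99 ± 0.14), ATP2C2-AS1 (-0.91 ± 0.13), RIMBP2 (-0.89 ± 0.14), MYZAP (-0.84 ± 0.15) and GLDN (-1.05 ± 0.19). Further probe sets of MIER2, ACKR5 and GLDN did not share the sign, nor did 1 of the 2 further probe sets of H2AX (-0.28). H2AX had a signal of 66.9 ± 6.42 in saline and 159.8 ± 23.6 in siLNA (SD, n = 3). MIER2 stood at 7.03 and 36.7 and ANKRD36B at 36.2 and 88.2. Of these named genes, all except H2AX and ANKRD36B had a mean signal under the filter level of 10.9 in saline or in siLNA. With siRNA against the same saline arrays none passed and only MIER2 moved the other way (-0.23), while ARHGAP25 moved by 0.64, ANKRD36B by 0.53 and MYZAP by -0.53. When siLNA was set against siRNA, MIER2, H2AX and RIMBP2 passed and the others did not.

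The count of 0 rested on siLNA replicate 3, without which 57 probe sets passed, 51 higher and 6 lower, with H2AX at adjusted p = 0.0395. It was 15 with an intensity trend and 6 with a pseudocount of 64. The small-subunit ribosomal RNA control at its 3' end read 457 and 488.3 on siLNA replicates 1 and 2 against 1678.2 on siLNA replicate 3 and 1931.4 to 2328.2 on the saline arrays.

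The hypoxia response was the list with the lowest median in siLNA tumours at -0.30, with 29 of 31 members below 0 and none past the threshold by either adjustment. Its camera adjusted p was 2.25e-05, and adjusted p = 0.727 with an estimated correlation. Its leading members were BNIP3L at -0.52, the peptide hormone gene ADM at -1.18, P4HA1 at -0.52 and TMEM45A at -0.88. Both RNAs were set against the same 3 saline arrays. Ribosomal protein genes had a median of -0.20 over 32 members (adjusted p = 1.25e-09, and adjusted p = 0.727 with an estimated correlation), with RPS3 at -0.41 and RPL12 at -0.34. That median became 0.011 under quantile normalization. The log2 of 3' over 5' signal for the ACTB control was 0.815 ± 0.366 on the siLNA arrays, with a lowest value of 0.472, against 1.08 ± 0.146 on the saline arrays, with a lowest value of 0.985 (SD, n = 3). The lower value means less 3' signal relative to 5' signal. For the GAPDH control the means were close, at 0.297 ± 0.184 on the siLNA arrays and 0.287 ± 0.036 on the saline arrays (SD, n = 3). Oxidative phosphorylation genes had a median of -0.15 over 32 members (adjusted p = 0.00272, and adjusted p = 0.727 with an estimated correlation), with COX7C at -0.36, ATP5MC1 at -0.35 and COX5A at 0.30. No member of the ribosomal or oxidative phosphorylation lists passed by either adjustment, and the call for oxidative phosphorylation was lost without siLNA replicate 2 (adjusted p = 0.0619) and under quantile normalization (median -0.048, adjusted p = 0.798).

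For siLNA, too, the lists tied to double-stranded RNA were not called and held no member past the threshold, over all genes or adjusted over the list alone. Interferon-stimulated genes had a median of 0.07 (adjusted p = 0.788), with IRF1 at 0.54 (adjusted p = 0.372), HERC6 at 0.34, PARP14 at 0.27 and IRF7 at -0.34. Double-stranded RNA sensing had a median of -0.07 (adjusted p = 0.337), with EIF2S1 at -0.45 and NLRX1 at 0.37. RNA interference machinery had a median near 0 (-0.004, adjusted p = 0.814), with MOV10 at 0.49, DICER1 at 0.35 and AGO4 at 0.31. NF-kB and inflammatory cytokine genes had a median of 0.01 (adjusted p = 0.337), with NFKB2 at 0.80, CSF1 at 0.61, LIF at 0.60 and CXCL2 at 0.51. On the myeloid list (median -0.21, adjusted p = 0.788) 1 gene rose when adjusted over that list alone.

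**Figure D3:**
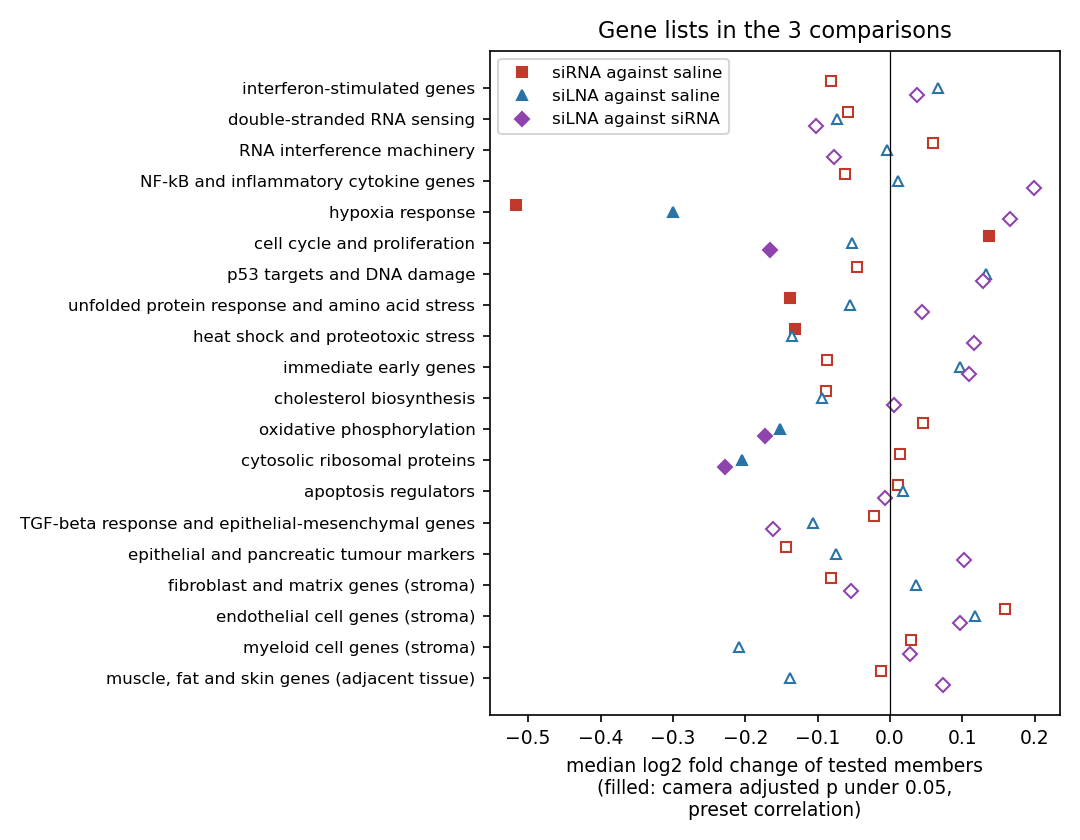
Median log2 fold change of each of the 20 lists tested (horizontal axis) in the 3 comparisons, marked by shape and colour, with filled symbols where camera with the preset correlation gave an adjusted p under 0.05. The hypoxia list lies lowest, at -0.52 for siRNA and -0.30 for siLNA, and none of the filled symbols stays called with an estimated correlation.

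The siRNA and the siLNA, given at the same dose against the same target, were compared directly, although their sequences are not given in the sources used here. In siLNA against siRNA 327 probe sets passed, 174 higher and 153 lower, and 5560 at an unadjusted p of 0.05. CLDN11 was lower in siLNA than in siRNA tumours by a log2 difference of -5.16 (95% interval -5.54 to -4.78), RTN1 of -4.48 (-5.05 to -3.91), GAS1 of -4.32 (-4.80 to -3.84) and SELENOP of -3.96 (-4.41 to -3.497). GJB2 was higher in siLNA by 2.75 (2.21 to 3.29), FRMD4B by 2.22 (1.89 to 2.55) and NAV3 by 2.18 (1.71 to 2.65). The other named genes higher in siLNA were the glutamate receptor gene GRIK2 (2.13), the calcium channel gene CACNA1A (1.99), ROBO1 (1.98), AMOTL1 (1.90), MDFIC (1.85), SLITRK6 (1.84), GAS2 (1.82), LOC646736 (1.82) and CDH18 (1.81). Named genes lower in siLNA were also ZNF488 (-3.26), TSPAN18 (-2.59), C6orf15 (-2.57), GNAL (-2.51), ADD3 (-2.19), TGFBR2 (-2.03), the amino acid transaminase gene BCAT1 (-2.02) and TANC1 (-1.87). Further probe sets of GAS1, AMOTL1 and MDFIC did not share the sign of the named ones.

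Of the 169 probe sets called for siRNA against saline, 130 also passed in siLNA against siRNA, all with the opposite sign, where independent lists would share 0.84. Both comparisons hold the same siRNA arrays, and the expected value does not allow for that. In the 169 the median absolute log2 change was 1.25 for siRNA and 0.17 for siLNA, both against saline. The siLNA interval excluded the siRNA change in 162 of them a 2-fold change in the siRNA direction in 154 and a change 0.5 times that of siRNA on the log2 scale in 118, although the 169 were chosen for a large siRNA change. The siLNA change had the sign of the siRNA change in 65.1%. Simulated siLNA arrays gave 52.1% to 69.8%, but they were centred on the mean of the saline and siLNA arrays. They thus carry part of the observed siLNA change, and this range cannot decide whether 65.1% exceeds the share with no effect. Across all tested probe sets, which are not independent replicates, the fold changes of both RNAs correlated at r = 0.35, against 0.50 simulated with no effect, and their covariance was 0.0363 against 0.0273 simulated. The simulation shares the saline arrays too, at a spread pooled over all groups. With 3 saline arrays, 2 cannot be given to each comparison, so a contribution of the shared arrays beyond that spread stays possible.

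**Figure D4:**
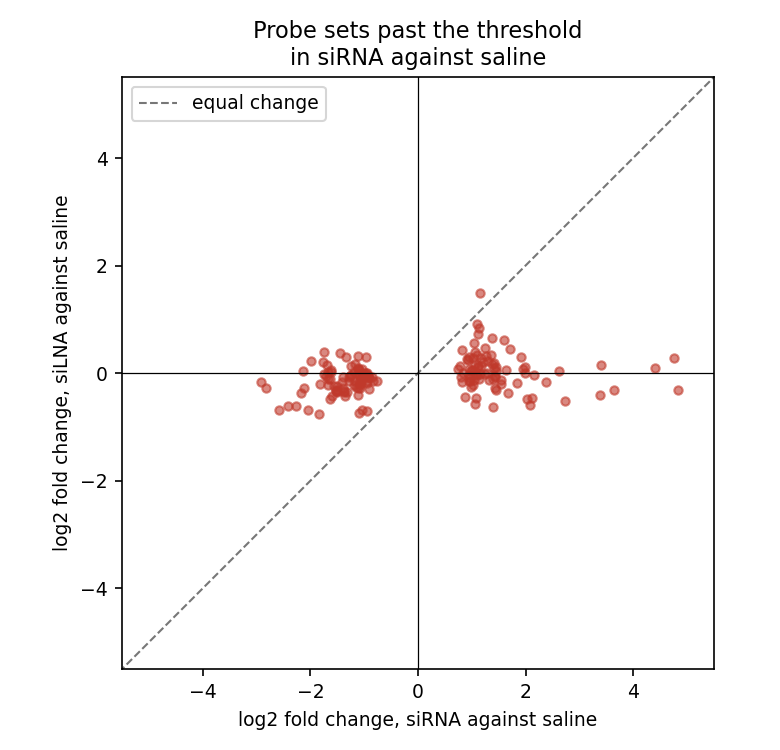
Log2 fold change against saline in siRNA tumours (horizontal axis) and siLNA tumours (vertical axis), with 1 point for each of the 169 probe sets past the threshold in siRNA against saline, and a dashed line where the changes would be equal. The points spread along the siRNA axis, with a median absolute change of 1.25, and lie close to 0 on the siLNA axis, with a median of 0.17.

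Between the RNAs, ribosomal protein genes were lower in siLNA (median -0.23, 32 of 32 below 0, adjusted p = 1.51e-06), as were oxidative phosphorylation genes (-0.17, adjusted p = 0.00414) and cell cycle genes (-0.17, adjusted p = 0.00414). Each of these 3 lists had adjusted p = 0.782 with an estimated correlation, and none held a member past the threshold by either adjustment. Under quantile normalization all 3 calls were lost, with the ribosomal protein median at -0.046 (adjusted p = 0.478). The ACTB 3' over 5' value was 0.815 on the siLNA arrays and 1.15 on the siRNA arrays, and the GAPDH value was 0.297 and 0.425. Leading members of the 3 lists were RPL12 (-0.48), ATP5MC1 (-0.54) and CCNE2 (-0.63). The hypoxia list did not differ past the threshold (median 0.17, adjusted p = 0.0771), and 2 of its genes rose when adjusted over the list alone. Outside the naming rule are SLC2A3 and the members of other lists given next, except TGFBR2. SLC2A3 stood at 1.04 (95% interval 0.58 to 1.497, adjusted p = 0.0515). In the TGF-beta list SKIL (-1.75), TGFBR2 (-2.03), TGFBR1 (-0.89) and TGFBI (-1.37) were lower in siLNA past the threshold and 15 of 19 genes did not pass, in a list not called by camera (adjusted p = 0.119). It was the list fry called (adjusted p = 0.016). FAS (1.22), the apoptosis gene PMAIP1 (1.25) and JUND (0.87) were higher in siLNA, and VCAN (-1.42) and KRT8 (-0.65) lower, each the lone member of its list to pass. The interferon, double-stranded RNA sensing, RNA interference and NF-kB lists again held no member past the threshold, with list adjusted p between 0.119 and 0.557. Adjusted over the list alone, the RNA interference gene AGO2 (0.73, adjusted p over all genes 0.0657) rose and the NF-kB gene IER3 (-0.78, 0.0543) fell.

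Calls in siLNA against siRNA were lost for CDH18 without any siRNA array or siLNA replicates 1 or 2 (adjusted p 0.0631 to 0.0811), and for TSPAN18 without siRNA replicates 1 or 3 or siLNA replicate 2 (0.0505 to 0.0642). LOC646736 lost its call without siRNA replicate 1 or siLNA replicate 2 (0.0543 to 0.0618), GNAL without siRNA replicate 1 (0.0537), and CACNA1A (0.0509) and TGFBR2 (0.0555) without siLNA replicate 2. With a pseudocount of 1 the calls for ZNF488 (0.0747), TSPAN18 (0.0916), GNAL (0.0629) and TGFBR2 (0.0521) were lost. The count of 327 fell to 50 without siLNA replicate 2, to 56, 69 and 79 without siRNA replicates 1, 2 and 3, to 78 without siLNA replicate 1 and to 195 and 197 without saline replicates 1 and 2, and rose to 596 without siLNA replicate 3. Calls for cell cycle and oxidative phosphorylation were lost without siRNA replicate 3 or siLNA replicate 2 (adjusted p between 0.0531 and 0.156).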

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

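Chosen only after their results had been seen were the tests of RNA quality, of the share of rises, of probe sets without a single named gene and of the share of calls on chromosome 9. The tests of neighbouring genes, of other cell types and of siLNA replicate 3 were set before.

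The siRNA and siLNA tumours differed by a direct test in 327 probe sets. Of the 24 genes named for siRNA against saline, 23 were past the threshold in siLNA against siRNA. The 24 were chosen for large changes on the same siRNA arrays, so a high number was likely beforehand and adds no separate support. The log2 difference, siLNA minus siRNA, was -5.16 for CLDN11, -4.48 for RTN1, -4.32 for GAS1, -3.96 for SELENOP, -3.26 for ZNF488, -2.57 for C6orf15, -2.19 for ADD3, -2.59 for TSPAN18, -2.51 for GNAL, -1.87 for TANC1, -1.87 for TLE2 and -2.03 for TGFBR2. It was 2.75 for GJB2, 1.90 for AMOTL1, 1.82 for LOC646736, 1.81 for CDH18, 2.18 for NAV3, 1.85 for MDFIC, 2.22 for FRMD4B, 1.08 for APOBEC3G, 1.63 for PKD1L1-AS1, 1.98 for ROBO1 and 1.74 for SCNN1A. The gene left over, DSC1, did not pass. Median differences of the called lists were -0.17 for cell cycle, -0.17 for oxidative phosphorylation and -0.23 for ribosomal proteins. Each of these lists had adjusted p = 0.782 with an estimated correlation, and all 3 calls were lost under quantile normalization, where the ribosomal protein median was -0.046.

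Splits of the 6 arrays of each comparison number 10, too few for a share under 0.05. The real split gave 169 probe sets for siRNA against saline, 0 for siLNA against saline and 327 for siLNA against siRNA, and the highest of the other splits gave 0 in each (1, 10 and 1 of the 10 splits reached the real count, the real one included). For any difference among the 3 groups, 100 of the 280 splits of the 9 arrays were counted. Of these 1, the real one, reached 205 probe sets, so a count as large was rare among groupings of these arrays. That bears on the count as a whole, not on each call. It cannot tell the treatment from another difference between the groups of tumours. The highest other split gave 200. The 4 other splits drawn that kept the siRNA arrays together gave 133 to 200 probe sets and the 95 that parted them gave 0, which points to the siRNA arrays as the structure behind these calls.

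The first pattern is the set of changes shared by all 3 siRNA tumours, 22 of the 169 of them at least 4-fold. Against RNA quality as a source of 4-fold changes stands a small 3' to 5' difference. In GAPDH and ACTB controls the siRNA arrays differed from saline by at most 0.138 on the log2 scale. The GAPDH value was nevertheless higher on every siRNA array (0.387 to 0.449) than on the saline arrays (0.246 to 0.316). Smaller effects of RNA quality thus stay open. A copy number difference over neighbouring genes may account for the shift on chromosome 9. The window median there reached 0.524 against 0.243 in the shuffles and 0.248 in the other splits. Those splits mix the groups and so dilute a shift. However, siLNA against saline also had a window, on chromosome 20 (0.305), above its shuffles (0.230) and its other splits (0.290). Only 11.9% of the placed siRNA calls lie on chromosome 9, but this share does not bear on effects of that shift on genes elsewhere. Chromosome 5 also stepped beyond every shuffle, so the other calls stay open. A different share of stroma or another cell type stays open, because the largest median among the 5 lists, -0.274, beyond the bound of 0.2 (0.274 in size), rests on 4 erythroid genes, and the other 4 medians lay within 0.159 of 0.

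The second pattern is the rises in the siRNA tumours. Direct silencing of partly matching transcripts predicts falls. Rises made up 49.7% of the calls, but this share counts the rises to be explained, so it decides nothing. Direct silencing with secondary effects, a difference between tumours that preceded treatment and another effect of the siRNA stay open, and seed matches were not tested.

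The third pattern is the excess of small shifts in the siLNA tumours, 3429 probe sets at an unadjusted p of 0.05 against up to 3082 in other splits of those arrays. Probe sets moved in siLNA replicates 1 and 2, the arrays with low ribosomal RNA control signal, moved the same way in siLNA replicate 3 in 56.7% of cases, between the bounds of 55% and 60% set before, and in 60.1% and 52.8% with another saline array held out, so a shift of those arrays alone stays open. Rising probe sets were 1.64 times as likely as all tested ones to name no single gene (32.7% against 20%), and falling ones 1.02 times. Such probe sets may include unspliced or non-coding RNA, for which the arrays hold no separate measure. RNA quality stays open too, with ACTB 3' over 5' values between 0.472 and 1.20 on the siLNA arrays against 0.985 to 1.24 on the saline arrays. The GAPDH values spread more widely on the siLNA arrays (0.084 to 0.408) than on the saline arrays (0.246 to 0.316), but their means were close (0.297 and 0.287). A biological effect of the siLNA stays open and untested.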

How the results depend on the processing

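Leaving out siLNA replicates 1 and 2 together was chosen after seeing the data, and all other alternatives before. The counts in this paragraph are of probe sets past the threshold for siRNA against saline (169), siLNA against saline (0), siLNA against siRNA (327) and any group difference (205). A pseudocount of 1 gave 64, 0, 95 and 50, and a pseudocount of 64 gave 789, 6, 1625 and 1476. Without the filter they were 102, 0, 139 and 96, and with the 60th percentile 453, 0, 947 and 626. An intensity trend gave 880, 15, 1834 and 1689. A fit of only the groups compared gave 61, 0 and 82, with fewer arrays to estimate the spread. Array weights gave 520 for siLNA against siRNA. Leaving out siLNA replicates 1 and 2 gave 64, 0, 10 and 19, but it leaves 1 siLNA array, with the spread taken from the other groups, so these counts do not show dependence on those arrays. Leaving out 1 array gave 34 to 134, 0 to 57, 50 to 596 and 29 to 400. Quantile normalization, median centring and robust eBayes kept each count within 1.5 times. Except where arrays or groups were left out, the cause of these differences was not tested.

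With the replicate number as a block the counts were 59, 0, 94 and 54, and 58 and 90 of the main calls for siRNA against saline and siLNA against siRNA were kept. The deviations of arrays with the same number correlated between -0.047 and 0.043, so the numbers do not pair the arrays, and 2 of the 9 arrays correlated best with their own number.

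Lists called numbered 4 for siRNA against saline, 3 for siLNA against saline and 3 for siLNA against siRNA. With an estimated correlation they were 0, 0 and 0, under fry 0, 0 and 1, and with the most variable probe set per gene 1, 1 and 0. Quantile normalization gave 1 for siLNA against saline and 0 for siLNA against siRNA, and its ribosomal protein median against saline reversed to 0.011. A pseudocount of 64 and the 60th percentile each gave 5 for siLNA against siRNA. Leaving out 1 array gave 1 to 4, 2 to 3 and 1 to 5. The cause was not tested. The correlation of the fold changes of both RNAs was 0.348, 0.399 without the filter and 0.260 with the 60th percentile.

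Named genes kept direction under every alternative run. Counting each gene under each alternative once, calls for siRNA against saline were lost 53 times and kept 451 times, those for siLNA against siRNA lost 35 times and kept 468 times, and genes of siLNA against saline gained a call 3 times and stayed without one 185 times.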

Other observations

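The scan of neighbouring genes was set before, and the tests of the turn, of single arrays and of called genes on chromosome 9, with the genes named here, were chosen after its result was seen. Before the turn MPDZ (log2 fold change -1.67), ADAMTSL1 (-1.34) and the lipid droplet gene PLIN2 (-1.05) fell. After the turn CEMIP2 (1.70), OLFML2A (1.37), MIRLET7D (1.11), the endocytic GTPase gene DNM1 (1.09), BRD3 (1.03), TRIM14 (1.01), the condensin gene SMC2 (0.99), GOLM1 (0.80) and FBXW2 (0.75) rose. In siLNA against siRNA 28 genes of that chromosome were called, 3 higher before the turn and 25 lower after it, 15.2% of the 184 placed calls. Over all chromosomes 65 of those 184 had another called gene within 10 places, against a median of 42 in shuffles (3 of 1000 as many). Means of the siRNA array medians were -0.36 before and 0.39 after the turn as deposited, and -0.37 and 0.38 after quantile normalization.

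A window of 50 neighbouring genes on chromosome 20, from LSM14B to RGS19, stood 0.37 and 0.41 above the saline mean on siLNA replicates 1 and 2 and 0.08 above it on siLNA replicate 3. The siRNA arrays lay between -0.009 and 0.069 there.

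A hypothesis from these values was found in these same data and has no separate test in them. By it the siRNA tumours grew from a MIA PaCa-2 population that differed on chromosome 9 from the cells of the other 6 tumours. That population would hold less of the short arm and more of the long arm. A difference of that kind could precede treatment. Some of the large changes, the rise of GAS1 among them, may then belong to the cells rather than to the siRNA. GAS1 rose by 4.41 on the log2 scale, against a median of 0.39 over the genes after the turn. The shift of the arm alone does not give a change of that size, and the second GAS1 probe set did not share the rise. The window median of 0.524, beyond all 1000 shuffles and the other splits of the siRNA and saline arrays, prompted this hypothesis. It is therefore no separate test of it. The other splits mix the groups and so dilute a shift, and 10 splits cannot give a share under 0.1. The siRNA arrays all carry the shift and the 6 others do not, so no comparison in these data separates the cells from the treatment. DNA from the tumours was not analysed here.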
